A study of Homo sapiens with 8 samples.

How the data were processed

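Total RNA of 8 KCL-22 libraries (1 vehicle population, 3 resistant populations and 4 clones) was prepared with RNeasy Plus Mini columns and sequenced on an Illumina instrument. The deposited values are FPKM, computed by the authors, with 1 value per gene and library. The submitters' processing notes name TopHat 1.3, Cufflinks 1.3 and GRCh37. The unit is not named in the table's header and was taken from the tool and from the values, which are not whole numbers and sum to between 497775 and 583520 per library.

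The table holds 31402 entries, 7932 of them known only by a transcript identifier. A value was not given in at least 1 library for 70 entries, MYB, QKI and IKZF1 among them, and these were left out. All 19 mitochondrial entries were 0 in every library, so the mitochondrial list gave no value. Of 23470 Entrez identifiers, 23286 matched the reference gene table, which was used for biotype, and GENCODE release 29 gave the intronless genes. Transcript length and GC content were found for 11330 of the tested genes (95.7%) from the transcripts of the same GENCODE release, on GRCh38. Positions are those of the deposited table. Genes with a mean FPKM of at least 1 over the 8 libraries were kept, which left 11843 genes; 401 of these were listed at 0 in at least 1 library, and 297 of the 401 had 5 or more in another.

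No read counts were used here. Depth was estimated from 666 intronless genes 1000 to 8000 bases long, as the smallest step of FPKM times length, which 1 fragment gives. The estimates were 28100000 fragments for the vehicle population, 36000000 for the imatinib population, 31800000 for the nilotinib population, 20100000 for the GNF-2 population, 40300000 for Clone 1, 24300000 for Clone 2, 26500000 for Clone 3 and 22000000 for Clone 4. They rest on the lowest peak of the values and are rough. The 10 most abundant genes took 6.86% to 10.36% of the FPKM sum, and 11258 (Clone 1) to 12025 (GNF-2 population) genes had an FPKM of at least 1.

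Libraries were grouped by resistance as the labels give it. On log2(FPKM + 1), limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 8 libraries (lmFit and eBayes with a trend of variance on mean), and contrasts were called at a Benjamini-Hochberg adjusted p of 0.05, two-sided. Only 2 groups have replicates, so 4 residual degrees of freedom carry the spread, and vehicle and Clone 4 are assumed to vary like the others. The same model with 1 mean per kind tested the clones against the resistant populations, a comparison added after seeing the data. Of 29 gene lists fixed in advance, 27 had at least 3 tested members. These were tested with camera at a preset correlation of 0.01 and again with an estimated one, adjusted over the lists of a contrast, two-sided. Members were also adjusted over the list alone. Single libraries were compared by counts of genes at least 2-fold apart with an FPKM of at least 5 in the higher one, with no test. List medians between single libraries were set against 10000 random lists matched for level, drawn gene by gene without leaving out list members. Distances between libraries are SDs of the log2 difference, compared by exact permutation of the group labels. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

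Genes to name were chosen by rule. For a tested contrast these were the 12 largest increases and the 12 largest decreases among genes past the threshold whose groups did not overlap. Where fewer than 5 passed in a direction, the 5 non-overlapping genes with the smallest p were taken and reported as not passing. For single libraries the rule took the 10 largest differences each way, and for all 7 resistant libraries the 12 largest each way. For each list it took the members past the threshold and then up to 4 by size of change. ABL1 and BCR were always included, and protein-coding genes with a known symbol were preferred. The same rule restricted to genes above 0 in all 8 libraries was added after seeing the data, because many of the largest changes were values of exactly 0 whose origin is not given in the sources used here. A few genes outside the rule were named after their values were seen: SLC2A1, VEGFA, MYC, ISG15, TREM1, IER5, PTGS2, HGF and IKZF1. For each clone, genes furthest outside the range of the other 7 libraries were also named, a choice that the rule did not hold.

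Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter or a mean FPKM of at least 5, rescaling by median ratios, quantile normalization, clone against population as a covariate, variance without trend or robust, an adjusted p of 0.01, a model with 1 term for each kind of resistance, and leaving out each replicate. Alternatives added later were only genes above 0 in all 8 libraries, removal of each library's length and GC trend, resistance group as a covariate, population of origin as a block, vehicle counted among the populations, list tests without each library or with clone as a covariate, and distances with labels permuted within clones and within populations. The pipeline was tested on simulated data of the same design, with each gene drawn independently and changes placed only in genes of higher level. Between the resistance groups it recovered 31 of 100 genes moved 2-fold and 85 of 100 moved 4-fold, with 10 of 11643 unmoved genes called. Between clones and populations it recovered 40 and 90 of 100, with 5 unmoved genes called. Barcode sequences, splice variants and the fusion transcript were not analysed here, and a few genes that the rule names are left out of the text.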

Results

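RNA was sequenced from 8 libraries of KCL-22, a human chronic myeloid leukemia line in blast crisis that carries the BCR-ABL fusion kinase. The cells had been tagged with ClonTracer, a lentiviral library of DNA barcodes that marks the descendants of single cells. Vehicle population cells (1 library) had been kept in 0.1% DMSO for 7 days. Resistant populations had grown out under imatinib at 2.5 µM for 27 days, nilotinib at 0.3 µM for 27 days or GNF-2 at 2.5 µM for 21 days, with 1 library each. Imatinib and nilotinib are structurally related inhibitors of the catalytic site of ABL, and GNF-2 is an allosteric inhibitor that binds outside it. The other 4 libraries came from clones sorted as single cells and expanded. Clone 3 came from an imatinib-resistant population and is resistant to imatinib and nilotinib. Clones 1 and 2 came from a GNF-2-resistant population and had never met a catalytic inhibitor, and Clone 4, of the same origin, is resistant to all 3 compounds. The libraries therefore fall into vehicle (n = 1), catalytic-inhibitor resistant (n = 3), GNF-2 resistant (n = 3) and resistant to all (n = 1).

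Values are FPKM, fragments scaled by transcript length in kilobases and by the mapped fragments of the library. Depth was estimated from the size of the smallest step between values of intronless genes, and ranged from about 20100000 fragments in the GNF-2 population to about 40300000 in Clone 1. That is roughly 40 to 81 fragments for a transcript of 2 kilobases at an FPKM of 1. Each condition has 1 library, so comparisons of single libraries have no replicate check, and no source used here says that libraries of a group came from separate cultures. The p-values below therefore measure only the spread between these samples.

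Both genes joined in the fusion were abundant in every library. ABL1, a tyrosine kinase gene on chromosome 9 (133589267 to 133763062, GRCh37), had an FPKM of 105 in vehicle, 110.5 in the imatinib population, 86.6 in the nilotinib population and 81.7 in the GNF-2 population. In the clones ABL1 lay between 65.3 (Clone 1) and 96.8 (Clone 4). BCR, on chromosome 22 (23522551 to 23660224), had 87.5 in vehicle and between 58.8 (Clone 3) and 106 (Clone 4) in the resistant libraries. Neither gene passed the limma test between the catalytic-resistant and GNF-2-resistant groups (ABL1 log2 difference 0.25, SE 0.21, adjusted p = 0.86; BCR 0.10, SE 0.23, adjusted p = 0.933). Gene-level values do not separate the fusion transcript from the normal alleles.

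The first question was how the libraries resemble each other. The first principal component, with 38.9% of the variance, ran from the vehicle population (44.9) through the imatinib (37.8), nilotinib (26.8) and GNF-2 (20.2) populations to the clones, which lay between -16.4 (Clone 3) and -38.7 (Clone 1). The second, with 19.1%, set Clone 2 (51.5) apart from Clone 3 (-32.7) and Clone 4 (-26.9). Between libraries of different inhibitor class the SD of the log2 difference averaged 0.721, against 0.698 within a class (SD 0.116). That difference of 0.0231 was matched by 2 of the 10 splits of the 6 libraries (exact permutation test, one-sided, p = 0.2; the smallest possible is 0.1). Those splits ignore that each class mixes clones and populations, and with labels permuted within each kind 1 of 9 splits, the real one, gave as much (exact permutation test, one-sided, p = 0.111, the smallest possible). Between clones and resistant populations the mean was 0.785, against 0.659 within them (exact permutation test, one-sided, p = 0.057, 2 of 35 splits). Clone 1 lay equally near the GNF-2 and nilotinib populations (0.762 each) and Clone 4 was nearest the GNF-2 population, its origin (0.762). Clone 2 was as near the nilotinib population (0.806) as its origin, the GNF-2 population (0.807). Clone 3 was nearer the nilotinib population (0.709) than the imatinib population (0.735).

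**Figure D1:**
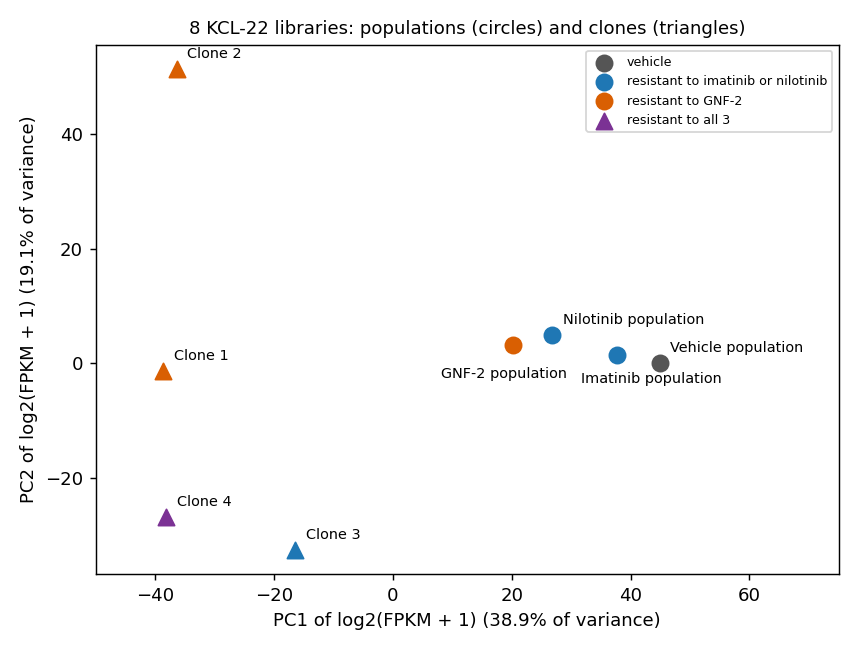
First and second principal components of log2(FPKM + 1) over 8 libraries, with their shares of the variance, 38.9% and 19.1%; circles are populations, triangles are clones and colours are resistance groups. The 4 populations sit between 20.2 and 44.9 on the first component and the 4 clones between -38.7 and -16.4.

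Genes at least 2-fold apart were counted between single libraries. Among genes with an FPKM of at least 5 in the higher library, 288 differed between the imatinib population and vehicle, 438 between the nilotinib population and vehicle, and 691 between the GNF-2 population and vehicle. The nilotinib and GNF-2 populations differed from each other at 227 genes, fewer than any other pair. By the SD of the log2 difference the nearest pair was instead the imatinib population and vehicle (0.445, against 0.465 for the nilotinib and GNF-2 populations). Each clone differed from its population of origin at 999 (Clone 1), 1171 (Clone 2), 1046 (Clone 3) and 1122 (Clone 4) genes, and from vehicle at 1260 (Clone 3) to 2067 (Clone 4). No source used here says that the sequenced population was the culture a clone was sorted from. Pairs of clones differed at 604 (Clones 1 and 3) to 1147 (Clones 2 and 4) genes.

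**Figure D2:**
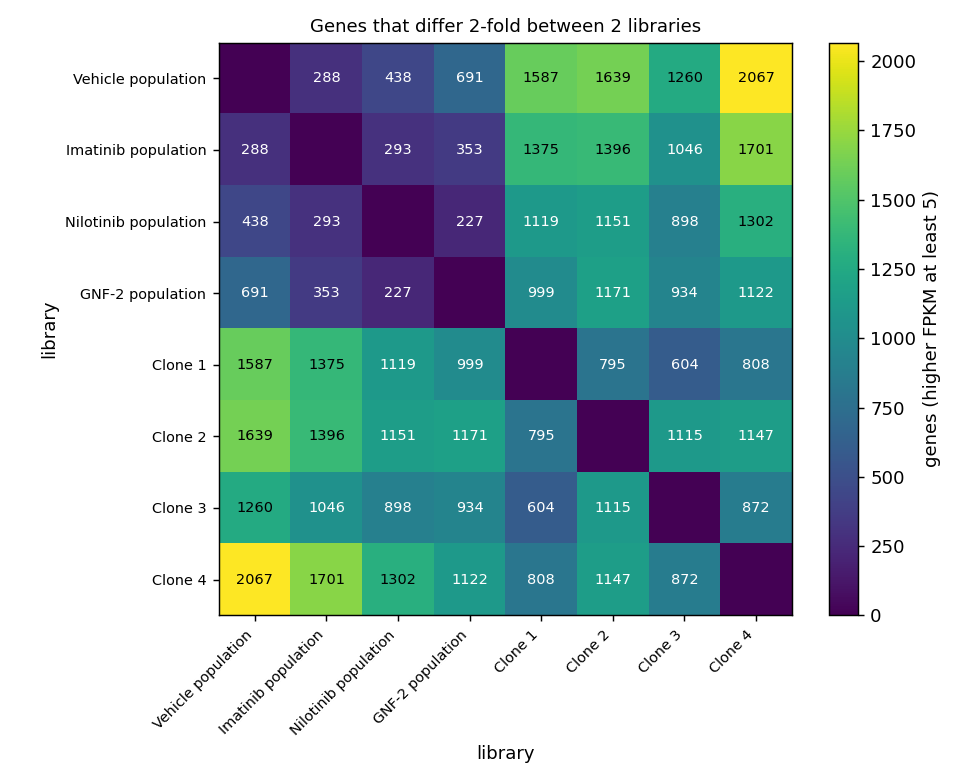
Number of genes at least 2-fold apart between each pair of the 8 libraries, among genes with an FPKM of at least 5 in the higher one. Pairs of populations give 227 to 691 genes and pairs with at least 1 clone give 604 to 2067.

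The comparison with vehicle asks which transcripts set the populations that grew out under each inhibitor apart from cells that met none. In the imatinib population, SIGLEC6, a sialic acid-binding receptor, had an FPKM of 12.3 against 118 in vehicle. OSM, the cytokine oncostatin M and a STAT5 target, had 5.33 against 40.6. EGR1, an immediate early transcription factor downstream of MAP kinase, had 7.33 against 44.1, and the semaphorin SEMA7A had 1.59 against 13.7. ALOX5AP, needed for leukotriene synthesis, had 18.6 against 107, and the calcium-binding protein S100A11 had 55.7 against 292. Higher than vehicle were N-cadherin (CDH2, 10.3 against 0.99), the Notch ligand DLL1 (6.27 against 0.60), the interferon-induced IFI27 (366 against 82.5), the phosphatase PTPRU (49.4 against 14), AIF1L (26.0 against 4.64) and the transcription factor SOX18 (57.8 against 17.5). Of the 288 genes, 87 were higher and 201 lower. Among the gene lists, BCR-ABL and STAT5 output was lower for 14 of 15 genes (median log2 difference -0.70), MAPK feedback and immediate early genes for 16 of 17 (median -0.59) and cell cycle genes for 25 of 25 (median -0.27). Interferon response genes were higher for 20 of 23 (median 0.49) and cholesterol synthesis genes for 16 of 17 (median 0.40). Glycolysis and hypoxia genes were split, 13 of 19 lower and 6 higher (median -0.18). Of the lists kept as signs of RNA quality and selection, ribosomal proteins were higher for 19 of 20 (median 0.19) and replication dependent histones for 7 of 8 (median 0.49). Each of these medians lay in the outermost 1% of 10000 random lists of the same size and level, which describes those libraries only. So did each list difference given below for single libraries, unless a percentile stands beside it. The random lists were drawn gene by gene, while members of a fixed list can vary together (estimated correlation 0.737 for interferon response and 0.425 for glycolysis and hypoxia). Such lists can lie far out between any 2 libraries, so these places are no test.

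In the nilotinib population CXCR4, the receptor for the chemokine CXCL12, had 1.94 against 53.4 in vehicle and adrenomedullin (ADM), a hypoxia-induced peptide, had 6.21 against 108. INHBA, a subunit of activin, had 0.09 against 7.17, the oxysterol receptor GPR183 had 2.77 against 22.6 and the potassium channel KCNH2 had 0.39 against 8.21. Higher were the osteoblast transcription factor SP7 (12.9 against 0.28), the water channel AQP1 (14.8 against 0.95), FGFBP2 (57.3 against 8.52) and CHAC1, a glutathione-degrading enzyme induced by ATF4 (36.0 against 5.93). IFI27, higher than vehicle in the imatinib population, was lower here (12.6 against 82.5). Of the 438 genes, 236 were higher and 202 lower. Glycolysis and hypoxia genes were lower for 18 of 19 (median -0.61), MAPK feedback genes for 15 of 17 (median -0.64) and cell cycle genes for 24 of 25 (median -0.53). MYC targets and ribosome biogenesis genes were higher for 19 of 22 (median 0.31), ribosomal proteins for 20 of 20 (median 0.28) and histones for 7 of 8 (median 0.48, percentile 98.7 of random lists). Unlike in the imatinib population, BCR-ABL and STAT5 output was split, 8 of 15 lower and 7 higher (median -0.12, percentile 6.0). Cholesterol synthesis genes were lower for 12 of 17 (median -0.30).

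The GNF-2 population had ADM at 2.23 against 108 and CXCR4 at 1.72 against 53.4. The glycogen-targeting subunit PPP1R3C had 1.22 against 16.4, CD4 had 2.27 against 24.3 and the heat shock gene HSPA1B had 17.0 against 221, although HSPA1B has a near-identical copy and its assignment is uncertain. Higher were SP7 (5.43), AQP1 (8.67), CHAC1 (33.1), AIF1L (24.5) and the cell cycle inhibitor CDKN2A (16.5 against 3.23). Of the 691 genes, 370 were higher and 321 lower. Glycolysis and hypoxia genes were lower for 19 of 19 (median -1.02), with the carbonic anhydrase CA9 at 28.6 against 93.8 and the glucose transporter SLC2A1 at 47.4 against 239. MAPK feedback genes were lower for 13 of 17 (median -0.83). Interferon response genes were higher for 22 of 23 (median 0.70), ATF4 and amino acid response genes for 15 of 19 (median 0.63) and MYC targets and ribosome biogenesis genes for 21 of 22 (median 0.79). Ribosomal proteins were higher for 20 of 20 (median 0.25), and histones were evenly split, 4 of 8 higher (median 0.14, percentile 40.62). MYC itself, a transcription factor that drives growth, had 343 against 127 in vehicle.

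All 7 resistant libraries were at least 2-fold below vehicle for 45 genes, 35 of them above 0 in all 8 libraries. Among the 45 were members of the glycolysis and hypoxia list: CA9 (93.8 in vehicle, 0 to 28.6 in the resistant libraries), ADM (108; 2.13 to 34.5) and the glucose transporter SLC2A3 (373; 97.2 to 152), which shares sequence with SLC2A14 and is uncertain to that extent. Others were SEMA7A (13.7; 0.13 to 1.69), CXCR4 (53.4; 0.03 to 18.0), the survival gene BCL2A1 (22.6; 0.40 to 7.93), OSM, INHBA, GPR183 and the myeloid receptor TREM1. Of the MAPK feedback and immediate early list 3 genes were among the 45 (EGR1, FOS and JUN), and of the NF-kB and cytokines list 0. IER5, PTGS2 and PPP1R15A (333; 41.5 to 158) were lower as well. ARG1, the urea cycle enzyme arginase, had 7.67 in vehicle and 0 to 0.28 elsewhere, and C10orf10 (DEPP, a FOXO-regulated gene) had 43.8 against 5.27 to 9.26. Only 9 genes were at least 2-fold higher in all 7, and 8 of the 9 were listed at 0 in vehicle. With another library as the reference, 3 (imatinib population) to 141 (Clone 2) genes were higher in that library than in all others; Clone 4 gave 88, the nilotinib population 13 and the GNF-2 population 14. Among the 4 populations alone, 95 genes were higher in vehicle than in the other 3, against 17, 42 and 34 with the imatinib, nilotinib and GNF-2 populations as the reference. Lower in the reference were 49 genes for vehicle, against 33, 20 and 50 in the same order. These 7 comparisons share the 1 vehicle library.

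**Figure D3:**
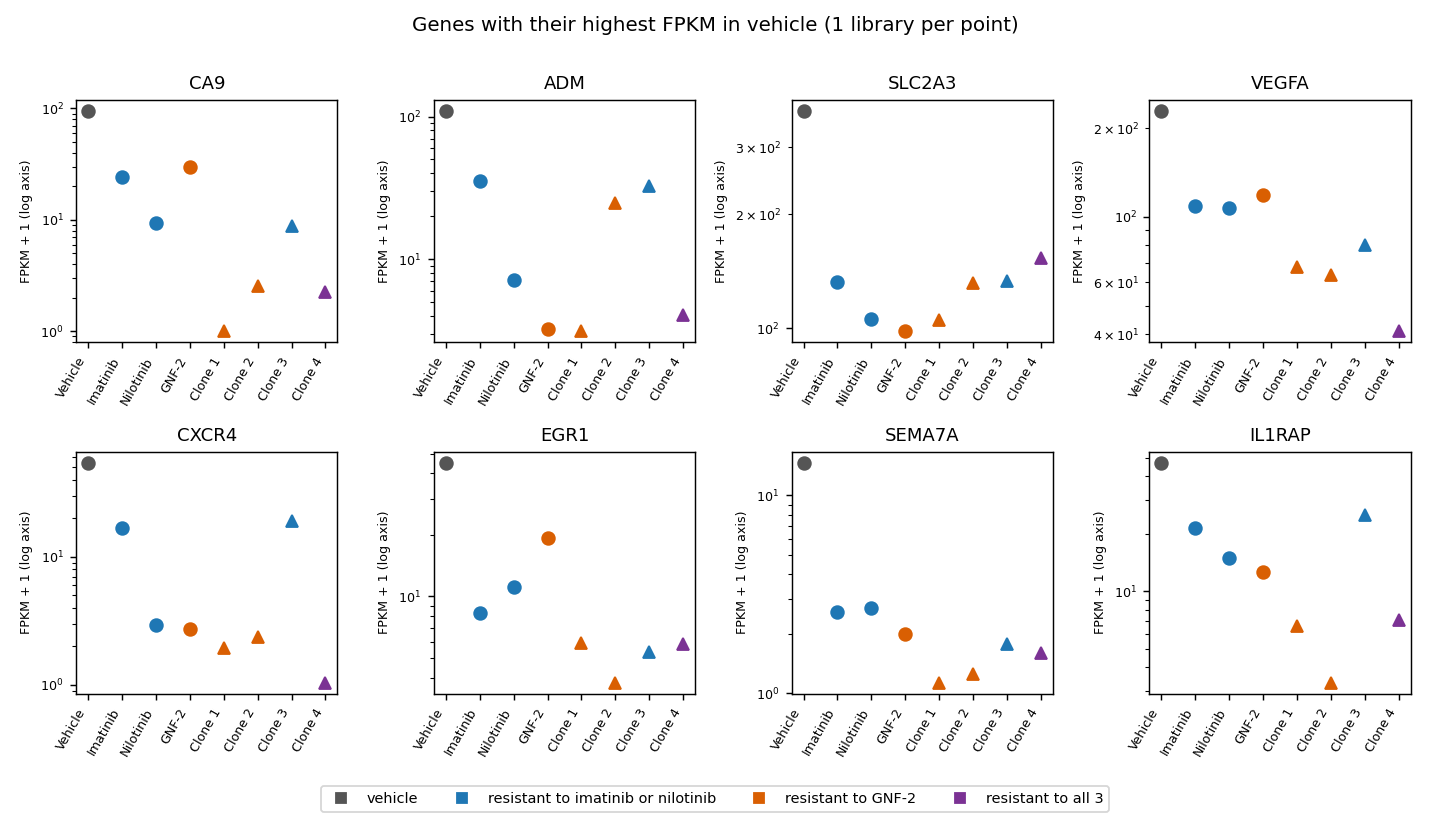
FPKM + 1 on a log axis for CA9, ADM, SLC2A3, VEGFA, CXCR4, EGR1, SEMA7A and IL1RAP, with 1 point per library; circles are populations and triangles are clones. Vehicle is the highest library for each gene, for example at 108 for ADM where the other 7 lie between 2.13 and 34.5.

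Replicated groups were then tested against the 1 vehicle library, which the model assumes to vary like the resistant libraries. In the GNF-2-resistant group (n = 3) STBD1, which anchors glycogen to membranes (chromosome 4, 77227178 to 77232283), fell to an FPKM of 10.2 ± 0.095 (SD) from 53.6 in vehicle (limma log2 fold change -2.29, SE 0.21, adjusted p = 0.0259). NET1, a RhoA guanine exchange factor (chromosome 10, 5454517 to 5500426), fell to 43.8 ± 1.97 (SD) from 160.2 (-1.85, SE 0.19, adjusted p = 0.0405). CYTIP, which controls leukocyte adhesion, fell from 23.6 to 0.53 (GNF-2 population), 0.73 (Clone 1) and 0.02 (Clone 2), with an adjusted p of 0.0294 in limma. Next in the same direction, without passing, came C10orf10 (log2 fold change -2.53, limma adjusted p = 0.0557), the UDP-glucose enzyme UGP2 (-1.30, 0.115) and PPP1R15A (-2.48, 0.115). On the higher side the imprinted RNA H19 (1.83, 0.157) and the pro-apoptotic BIK (2.37, 0.362) did not pass. In all, limma called 11 genes, 6 higher and 5 lower, and 9 of them were listed at 0 in at least 1 library. QTRT1, for example, was listed at 0 in vehicle and at 14.75 to 22.19 elsewhere, and GBGT1 at 0 in vehicle and at 10.97 to 19.2 elsewhere. At an unadjusted p below 0.05 there were 1315 genes (11.1%), and 7104 genes (60%, where chance gives 50%) did not overlap vehicle. With only genes above 0 in all 8 libraries limma called 0 (1284 at an unadjusted p below 0.05). The count became 7 without the imatinib population, 4 without the nilotinib population, 7 without Clone 3, 1 without Clone 1 and 3 without Clone 2.

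For the catalytic-resistant group (n = 3) the lower genes with the smallest p, apart from SNORA27, were C10orf10 (log2 fold change -2.31, limma adjusted p = 0.194), NET1 (-1.39, 0.285), ARG1 (-2.93) and CYTIP (-2.79). These did not pass the threshold, nor did STBD1 (-1.27), SLC2A3 (-1.61) or the mRNA decay factor ZFP36 (-1.38). Of higher genes, the demethylase HR (1.64), CMTM8 (0.91), the ion channel ACCN2 (1.34) and the cell cycle factor E2F5 (1.45) also did not pass. The 4 genes limma called (3 higher, 1 lower) were all listed at 0 in some libraries. They were QTRT1, GBGT1 and LOC100128881, listed at 0 in vehicle and above 0 in the 7 resistant libraries, and SNORA27, listed at 18.78 in vehicle and 0 elsewhere. At an unadjusted p below 0.05 there were 319 genes (2.7%), and 5924 (50%, the share chance gives) did not overlap vehicle. The count of 4 fell to 0 without the imatinib population, the nilotinib population, Clone 3, the GNF-2 population or Clone 1, and to 1 without Clone 2. With only genes above 0 in all 8 libraries it was 0 (304 at an unadjusted p below 0.05).

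The fixed gene lists were tested with camera. Glycolysis and hypoxia genes were below vehicle for 19 of 19 members in both groups, with a median log2 difference of -1.59 in the GNF-2-resistant group (camera adjusted p = 1.11e-12; adjusted p = 0.581 with an estimated correlation). In the catalytic-resistant group the median was -0.79 (adjusted p = 1.82e-09; adjusted p = 0.36 with an estimated correlation). No member passed over all genes, and adjusted over the list alone 7 members were lower in the GNF-2-resistant group and 1 in the catalytic-resistant group. Vehicle is a population and both groups hold clones, so these sizes include any difference between clones and populations. With clone as a covariate the medians of this list were -1.08 in the GNF-2-resistant and -0.53 in the catalytic-resistant group. SLC2A1 had 239 in vehicle and 47.4 to 144 in the resistant libraries, and the angiogenic factor VEGFA had 228 against 39.9 to 118. MAPK feedback and immediate early genes were lower for 17 of 17 in the GNF-2-resistant group (median -1.12, adjusted p = 5.07e-07; adjusted p = 0.581 with an estimated correlation) and 16 of 17 in the catalytic-resistant group (median -0.40, adjusted p = 2.99e-06; adjusted p = 0.36 with an estimated correlation). Of these, 5 passed in the GNF-2-resistant group when adjusted over the list alone. EGR1 had 44.1 in vehicle and 2.78 to 18.4 elsewhere, and JUN had 12.3 and 0.17 to 5.11. BCR-ABL and STAT5 output was lower for 12 of 15 members (median -0.59, adjusted p = 0.00154; adjusted p = 0.581 with an estimated correlation) and 11 of 15 (median -0.22, adjusted p = 0.0059; adjusted p = 0.497 with an estimated correlation). Adjusted over the list alone, 2 members were lower in the GNF-2-resistant group, and 0 over all genes. The kinase PIM1 had 132 in vehicle and 33.4 to 71.0 elsewhere, while MYC, also on this list, had 127 in vehicle and 182 to 343 elsewhere.

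Cell cycle genes were lower for 18 of 25 in the GNF-2-resistant group (median -0.66, camera adjusted p = 3.58e-05; adjusted p = 0.581 with an estimated correlation) and 22 of 25 in the catalytic-resistant group (median -0.49, adjusted p = 6.12e-09; adjusted p = 0.36 with an estimated correlation). CDK1, the mitotic kinase, had 139 in vehicle and 27.1 to 91.8 elsewhere. MYC targets and ribosome biogenesis genes were higher for 21 of 22 (median 0.88, adjusted p = 5.07e-07; adjusted p = 0.702 with an estimated correlation) and 20 of 22 (median 0.47, adjusted p = 6.79e-06; adjusted p = 0.497 with an estimated correlation). Among them SRM, the spermidine synthase, had 39.5 in vehicle and 51.0 to 115 elsewhere. With clone as a covariate the medians of the MYC list were 0.631 in the GNF-2-resistant and 0.315 in the catalytic-resistant group. Ribosomal protein genes, a list kept as a sign of RNA quality, moved the same way for 20 of 20 in both groups (medians 0.38 and 0.35, adjusted p = 0.0128 and 0.000407; adjusted p = 0.848 and 0.722 with an estimated correlation). Mast cell, basophil and eosinophil genes were lower for 5 of 5 in both (medians -1.07 and -1.10, adjusted p = 0.0311 and 0.00123; adjusted p = 0.581 and 0.36 with an estimated correlation). HDC, which makes histamine, had 684 in vehicle and 136 to 519 elsewhere. Adhesion and migration genes, CXCR4 among them, and FOXO targets were lower in both groups as well (medians -0.54 and -0.45 for adhesion, adjusted p = 0.00902 and 0.000529; medians -0.65 and -0.31 for FOXO, adjusted p = 0.0453 and 0.0259). With an estimated correlation these 4 gave adjusted p = 0.581, 0.36, 0.73 and 0.497. Of the 27 lists tested, 9 passed in the GNF-2-resistant group and 10 in the catalytic-resistant group, where NF-kB and cytokines was the tenth (median -0.35, adjusted p = 0.0128; adjusted p = 0.36 with an estimated correlation). In the GNF-2-resistant group FOXO targets failed with any library but Clone 2 left out (adjusted p = 0.0521 to 0.0747), mast cell genes without the GNF-2 population (0.0747) or Clone 2 (0.0535), and ribosomal proteins without Clone 1 (0.3). In the catalytic-resistant group BCR-ABL and STAT5 output failed without the imatinib population (0.327), and FOXO targets (0.335) and ribosomal proteins (0.0638) without Clone 3. With clone as a covariate 6 and 8 lists passed. Those lost were FOXO targets (adjusted p = 0.433 in the GNF-2-resistant and 0.287 in the catalytic-resistant group), ribosomal proteins (0.661 and 0.0551) and, in the GNF-2-resistant group, mast cell genes (0.0724). With an estimated correlation 0 lists passed in either group, and whether the 2 groups differ from each other is tested next.

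**Figure D4:**
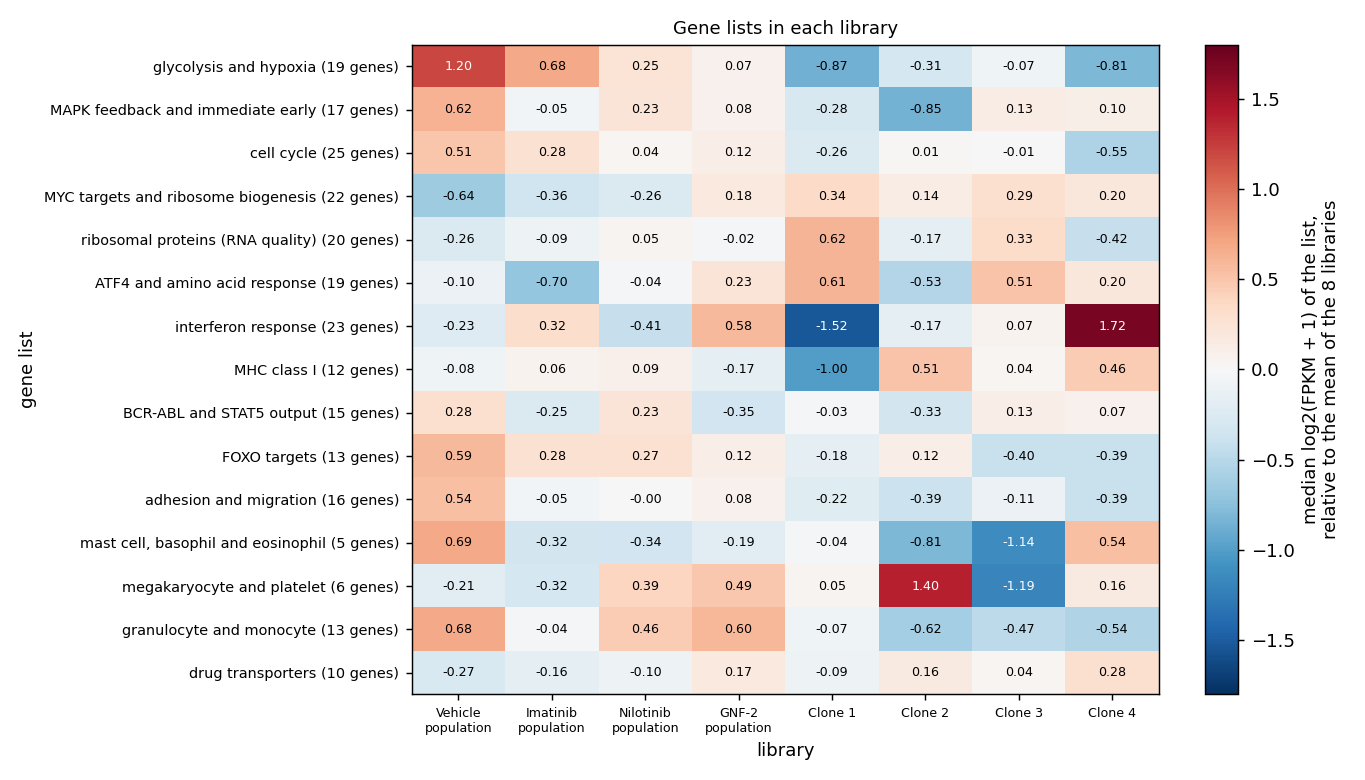
Median log2(FPKM + 1) of 15 gene lists in each of the 8 libraries, relative to the mean of the 8, as colour and printed value. Glycolysis and hypoxia genes are highest in vehicle (1.20), and interferon response genes range from -1.52 in Clone 1 to 1.72 in Clone 4.

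The central comparison of the design sets resistance to the catalytic inhibitors against resistance to GNF-2, 3 libraries each. The classes are not balanced, since the catalytic-resistant group holds 2 populations and 1 clone and the GNF-2-resistant group 1 population and 2 clones. Both clones of the GNF-2-resistant group came from a GNF-2-resistant population, and Clone 3 from an imatinib-resistant one. The 3 libraries of a class are therefore not independent, and class cannot be told apart from origin. PMP22, a myelin and membrane protein, had an FPKM of 47.3 ± 2.32 (SD) in the catalytic-resistant group and 20.9 ± 6.79 in the GNF-2-resistant group. SOCS1 and CISH, feedback inhibitors of JAK-STAT signalling, had 87.1 ± 30.9 against 20.1 ± 13.7 and 101.1 ± 18.4 against 49.6 ± 7.77. The Wnt agonist RSPO2 had 8.31 ± 2.83 against 0.768 ± 1.21 and TMEM158, a RAS-induced gene, 18.9 ± 18.0 against 0.521 ± 0.592. Higher in the GNF-2-resistant group were H19 (3.46 ± 0.437 against 11.4 ± 1.52), the endothelial receptor TIE1 (3.88 ± 0.482 against 9.57 ± 1.45), METTL7B (0.656 ± 0.295 against 3.58 ± 0.301) and the piRNA pathway gene TDRD9 (6.56 ± 3.55 against 43.5 ± 22.9). The nearest to the threshold of these was H19 (log2 difference -1.48, SE 0.19, limma adjusted p = 0.228), and STBD1 followed (1.02, SE 0.15, adjusted p = 0.347; 21.8 ± 2.80 against 10.2 ± 0.095). None of these genes passed.

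The 4 genes that limma called, 2 in each direction, were listed at 0 in whole groups of libraries. MRPS28, a mitochondrial ribosomal protein gene (chromosome 8, 80831094 to 80942506), was listed at 0 in vehicle, the imatinib and nilotinib populations and Clone 3, and at 31.9 (GNF-2 population), 42.7 (Clone 1), 32.6 (Clone 2) and 35.2 (Clone 4) elsewhere (adjusted p = 0.000532). GPANK1 was listed at 0 in the same 4 libraries and at 9.20, 10.7, 9.53 and 8.74 in the others (adjusted p = 0.00412). LIPT1, a lipoyl transferase gene, had 4.17 in vehicle, 4.80 in the imatinib population, 6.68 in the nilotinib population and 5.81 in Clone 3, and was listed at 0 in the other 4 (adjusted p = 0.0352). The fourth was the locus uc003tfx (adjusted p = 0.00336). At an unadjusted p below 0.05 there were 577 genes (4.9%), and 1291 (10.9%, where chance gives 10%) did not overlap, of which 160 differed 2-fold. With only genes above 0 in all 8 libraries limma called 0 (553 at an unadjusted p below 0.05). With clone as a covariate it called 3, without LIPT1. The count became 1 without the imatinib population, 9 without Clone 3 and 10 without the GNF-2 population.

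Of the gene lists, 6 passed camera with its preset correlation and 0 with an estimated one (adjusted p = 0.952 with an estimated correlation for each). Glycolysis and hypoxia genes were higher in the catalytic-resistant group for 19 of 19 (median 0.75, adjusted p = 1.01e-08), as with SLC2A1 at 144, 76.0 and 97.3 (imatinib population, nilotinib population and Clone 3) against 47.4, 49.99 and 65.6 (GNF-2 population, Clone 1 and Clone 2). MAPK feedback genes were higher for 13 of 17 (median 0.29, adjusted p = 0.003), interferon response genes for 22 of 23 (median 0.39, adjusted p = 0.0128) and MHC class I genes for 10 of 12 (median 0.27, adjusted p = 0.0304). MYC targets and ribosome biogenesis genes were lower for 19 of 22 (median -0.36, adjusted p = 0.000219). Megakaryocyte and platelet genes were lower for 5 of 6 (median -1.17, adjusted p = 0.0455), with the integrin ITGB3 at 90.1 in Clone 2 and 1.45 in Clone 3, and 1 member was lower when adjusted over the list alone. BCR-ABL and STAT5 output did not pass (median 0.01, mean 0.27, adjusted p = 0.0583), though 3 members, adjusted over the list alone, were higher. Clone 1 had the lowest levels of the 6 for interferon response (-1.52 relative to the 8-library mean) and MHC class I (-1.005), while the GNF-2 population (0.58) lay above the catalytic populations (0.32 and -0.41) for interferon and Clone 2 (0.51) was the highest of the 6 for MHC class I. Without Clone 1 neither passed (adjusted p = 0.589, in the other direction, and 0.608), nor without Clone 3 (0.31 and 0.295). Interferon response also failed without the imatinib population (0.0558), and MHC class I without the GNF-2 population (0.281). The MAPK list failed without Clone 2 (0.162) or Clone 3 (0.229), and the megakaryocyte list without the GNF-2 population (0.103), Clone 2 (0.262) or Clone 3 (0.31). Without Clone 3 only 2 lists passed, glycolysis and hypoxia and MYC targets, which passed with each library left out. Both lists also differ between clones and populations, in the sense that the unbalanced classes would give. With clone as a covariate both still passed (medians 0.53 and -0.24, adjusted p = 1.94e-08 and 0.0196; adjusted p = 0.974 with an estimated correlation for each). So did the MAPK, MHC class I and megakaryocyte lists (0.00404, 0.0157 and 0.0408), while interferon response did not (0.083). Whether the class difference itself differed between clones and populations could not be decided. The limma fit for it left 2 residual degrees of freedom, with 1 clone in the catalytic-resistant group and 1 population in the GNF-2-resistant group.

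Imatinib and nilotinib share a core structure, and both populations were kept for 27 days, at 2.5 µM and 0.3 µM, so their values can be set side by side but not tested. Among 293 genes at least 2-fold apart, 211 were higher in the nilotinib population. Higher there were the palmitoyl transferase ZDHHC2 (15.6 against 1.72), the receptor TNFRSF18 (14.4 against 1.57), resistin (RETN, 58.5 against 10.3), the elongation factor EEF1A2 (75.1 against 14.2), the B-cell receptor component CD79A (90.8 against 17.4) and GPR35 (36.3 against 7.30). Lower in the nilotinib population were IFI27 (12.6 against 366), NR2F2 (1.70 against 14.5), CXCR4 (1.94 against 15.6), ADM (6.21 against 34.5), CDH2 (1.59 against 10.3), MYCT1 (8.53 against 38.6) and the lipid droplet gene HILPDA (29.1 against 107). Interferon response genes were lower in the nilotinib population for 22 of 23 (median log2 difference -0.70), with OAS2 at 26.8 against 46.9. Cholesterol synthesis genes were lower for 16 of 17 (median -0.56). The glycolysis and hypoxia list was lower for 17 of 19 (median -0.33). ATF4 and amino acid response genes were higher for 17 of 19 (median 0.82), with CHAC1 at 36.0 against 7.91, and BCR-ABL and STAT5 output for 12 of 15 (median 0.53), with SOCS1 at 80.9 against 59.9. Ribosomal proteins, the sign of RNA quality, were higher for 18 of 20 (median 0.11), and histones were lower for 6 of 8 (median -0.02, percentile 24.9).

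Because clones and populations lay apart on the first component, the 4 clones were tested against the 3 resistant populations, a comparison added after seeing the data. The clones had more HSPA8, the constitutive HSC70 chaperone (chromosome 11, 122928199 to 122933186), which rose from 233 ± 6.17 (SD, n = 3) to 657 ± 93.3 (n = 4), a log2 difference of 1.48 (SE 0.15, limma adjusted p = 0.00359). TFRC, the transferrin receptor that brings iron into cells, rose from 26.1 ± 14 to 102 ± 28.1 (2.03, SE 0.38, adjusted p = 0.0258). S100A4, a calcium-binding protein linked to motility, rose from 342 ± 158 to 1186 ± 292 (1.85, adjusted p = 0.0231), and the folate carrier SLC19A1 from 15.2 ± 5.07 to 45.1 ± 8.51 (1.53, adjusted p = 0.0124). The metallothioneins MT1X and MT2A, which bind zinc and copper, fell from 698 ± 260 (SD) to 47.5 ± 34.3 (-4.04, SE 0.51, adjusted p = 0.00756) and from 1107 ± 483 to 97.6 ± 61.0 (-3.62, adjusted p = 0.0104); members of this family are near-identical, so the split of reads between them is uncertain.

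Further genes that rose in the clones were the endoplasmic reticulum chaperone partner SDF2L1 (1.36, limma adjusted p = 0.0213), the fatty acid transporter SLC27A4 (1.36, 0.0349), SMPDL3B (1.63, 0.0238), NXPH4 (1.37, 0.0329), B3GALT6 (1.34, 0.0445) and the RNA component of RNase MRP, RMRP (2.03, 0.0196). Genes that fell included TXNIP, an inhibitor of thioredoxin and of glucose uptake, from 243 ± 102 to 41.1 ± 11.7 (-2.50, SE 0.32, limma adjusted p = 0.00757). Tropomyosin TPM2 fell from 21.3 ± 1.13 to 2.05 ± 1.21, the cytoskeletal regulator DPYSL3 from 11.9 ± 5.13 to 0.369 ± 0.323 and the liprin PPFIA4 from 23.2 ± 5.0 to 2.08 ± 1.00 (adjusted p = 0.00313, 0.00436 and 0.00359). PAQR6, a membrane progestin receptor, fell from 19.1 ± 5.51 to 0.996 ± 0.306 (adjusted p = 0.000872), and GPR97 and SUSD4 fell as well (-3.18 and -3.10, adjusted p = 0.0450 and 0.0296). GOLGA8A and GOLGA8B, near-identical copies that cannot be assigned with certainty, fell by 3.83 and 2.95 on the log2 scale. Called list members that fell were JUN (-1.87, adjusted p = 0.0154), the cyclin CCND2 (-2.59, 0.0470), the kinase BTK (-1.37, 0.0321), HDC (-1.42, 0.0341), the G-CSF receptor CSF3R (-1.27, 0.0225), the integrin ITGAX (-1.66, 0.0263) and the neutrophil protease PRTN3 (-1.45, 0.0260).

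In total 870 genes passed, 198 higher and 672 lower in the clones, of which 51 and 365 differed at least 2-fold. Of the 870, 821 (94.4%) were above 0 in all 8 libraries. Among the other 49, AHSA2 was listed at 0 in the 4 clones and at 30.2, 28.4 and 32.4 in the imatinib, nilotinib and GNF-2 populations, and PIGW at 0 in the populations and at 4.90 to 6.21 in the clones. At an unadjusted p below 0.05 there were 3213 genes (27.1%), and 3111 (26.3%, where chance gives 5.7%) did not overlap. The direction split depends on scaling: the median log2 difference over all genes was -0.08 as deposited and 0.03 after quantile normalization, which gave 441 higher and 495 lower, and rescaling by median ratios gave 341 and 507. The count was 194 without the imatinib population, 120 without the nilotinib population, 248 without the GNF-2 population, 259 without Clone 1 and 550 without Clone 4. With population of origin as a block, which leaves out the nilotinib population, limma called 11 genes (3 higher, 8 lower). At an unadjusted p below 0.05 there were then 1919. The 870 genes kept their direction (870 of 870) and a median size of 0.95 against 0.98. They had been chosen for this difference in the same libraries, so this is no independent support.

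Of the gene lists, MYC targets and ribosome biogenesis were higher in the clones for 19 of 22 (median 0.38, camera adjusted p = 8.07e-06; adjusted p = 0.983 with an estimated correlation), with SRM rising from 62.0 ± 12.2 to 103 ± 11.8 (limma adjusted p = 0.0385) and BOP1, a ribosome assembly factor, from 8.97 ± 1.72 to 17.3 ± 2.76 (adjusted p = 0.0283). These 2 members passed over all genes and 7 when adjusted over the list alone. Those of glycolysis and hypoxia were lower for 16 of 19 (median -0.82, adjusted p = 0.00542; adjusted p = 0.983 with an estimated correlation), with the enolase ENO2 falling from 268 ± 103 to 61.1 ± 33.4 (limma adjusted p = 0.0424); 1 member passed over all genes and 10 adjusted over the list alone. Without the imatinib population 1 list passed, and that of glycolysis and hypoxia did not (adjusted p = 0.276). Lists that did not pass held single genes that did: TOP2A of the cell cycle list fell from 103 ± 14 to 59.2 ± 12 (limma adjusted p = 0.0444), with 1 member called and 10 adjusted over the list alone, and the drug exporter ABCC4 rose from 8.79 ± 1.78 to 17.1 ± 1.69 (adjusted p = 0.0213).

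**Figure D5:**
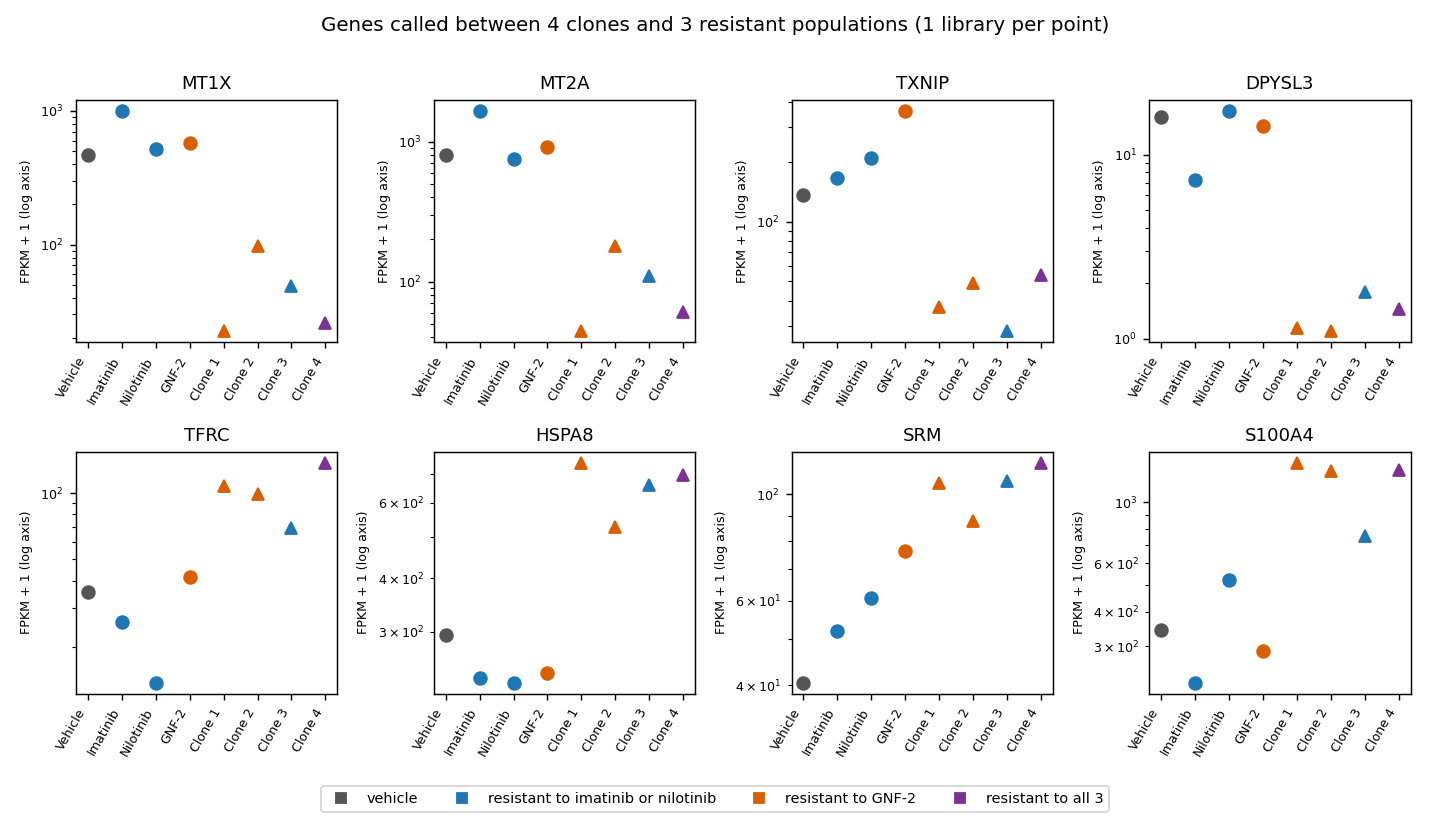
FPKM + 1 on a log axis for MT1X, MT2A, TXNIP, DPYSL3, TFRC, HSPA8, SRM and S100A4, with 1 point per library; circles are populations and triangles are clones. HSPA8 lies at 227 to 294 in the 4 populations and at 527 to 745 in the 4 clones.

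Clone 4, resistant to all 3 compounds and descended from a GNF-2-resistant population, was set beside both classes. Its interferon response genes were above the mean of the other 6 resistant libraries for 23 of 23 (median log2 difference 1.96), with the interferon-induced IFI27 at 1957, against 2.22 to 366 in the other 7 libraries. CMPK2 had 165 against 18.7 to 30.5, the antiviral enzyme RSAD2 126 against 10.8 to 23.2 and OAS2 171 against 4.72 to 74.6. MHC class I genes were higher for 12 of 12 (median 0.50), although HLA genes resemble one another and are uncertain singly. Of the lists kept as signs of RNA quality and selection, ribosomal proteins were lower for 20 of 20 (median -0.52, percentile 55.08 of random lists) and replication dependent histones higher for 6 of 8 (median 0.62). Ribosomal protein genes were not kept out of the random lists, so this percentile cannot say whether the shift is ordinary. The drug efflux pump ABCB1 had an FPKM of 10.4, against 0.36 to 1.81 in the other 7 libraries, and the detoxifying enzyme NQO1 had 54.9 against 4.18 to 12.8. Lower were VIM, the intermediate filament vimentin (49.5 against 233 to 966), and PGRMC1 (2.92 against 25.0 to 35.4). Cell cycle genes were lower for 23 of 25 (median -0.56) and glycolysis and hypoxia genes for 17 of 19 (median -0.78). At all 4 genes called between the classes Clone 4 lay nearer the GNF-2-resistant group. Of the 160 genes that did not overlap and differed 2-fold, Clone 4 lay nearer the catalytic-resistant group at 66 (41.2%) and nearer the GNF-2-resistant group at 94. The GNF-2-resistant group is of like origin and holds more clones than the catalytic-resistant group. Nearness therefore cannot be told apart from origin or from being a clone.

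Every clone had genes far outside the range of the other 7 libraries. Those given here with that range were picked for lying outside it. Genes at least 2-fold from all other libraries numbered 75 (Clone 1) to 250 (Clone 2) in the clones. Populations had them too, 54 in vehicle, 8 in the imatinib, 14 in the nilotinib and 20 in the GNF-2 population. Such genes are therefore not particular to descent from 1 cell. In Clone 1 interferon response genes were below the GNF-2 population for 23 of 23 (median log2 difference -2.00), among them TRIM22 (0.97 against 9.15 to 33.0 in the other 7 libraries) and OAS2 (4.72 against 23.7 to 171). Ribosomal proteins were higher there for 20 of 20 (median 0.61) and histones for 5 of 8 (median 0.27). Clone 1 had the anti-apoptotic BCL2 at 64.6 (5.1 to 26.4 in the others), the arginine-synthesis enzyme ASS1 at 626 (94.0 to 269.9), the immunoglobulin J chain IGJ at 187 (0.57 to 63.0) and the prostaglandin-degrading HPGD at 13.8 (0.28 to 3.12). In Clone 2 the Wnt ligand WNT11 had 37.9 against 0.57 in the GNF-2 population, the Fc receptor chain FCER1G had 323 (0.55 to 37.1 in the others), PCOLCE had 381 (2.21 to 24.9) and SP7 had 114 against 5.43. Granulocyte and monocyte genes were lower in Clone 2 than in the GNF-2 population for 10 of 13 (median -1.26), with the protease CTSG at 0.05 against 41.4, and ATF4 and amino acid response genes for 17 of 19 (median -1.20). Histones were higher in Clone 2 for 7 of 8 (median 0.55) and ribosomal proteins lower for 19 of 20 (median -0.11, percentile 83.4, with the limit given for Clone 4). In Clone 3 the xenobiotic-metabolising CYP1B1 had 329.6 (0.02 in Clone 2, 42.0 in the imatinib population), PROCR had 56.5 (1.56 to 11 in the others) and the prion protein gene PRNP had 117 against 9.56 in the imatinib population. The T-cell marker CD7 had 2.16 (27.3 to 112 in the others), and the 14-3-3 protein YWHAE had 39.8 (180 to 219). ATF4 and amino acid response genes were higher in Clone 3 than in the imatinib population for 18 of 19 (median 1.25), with PSAT1 of serine synthesis at 267 against 63.0, and MYC targets and ribosome biogenesis genes for 21 of 22 (median 0.64). Ribosomal protein genes, the sign of RNA quality, were higher there too, for 20 of 20 (median 0.42), and histones were split, 4 of 8 (median -0.16, percentile 38.43).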

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

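The tests of depth, of values at 0, of other libraries and other populations as the reference and of the glycolysis and hypoxia list without its lower members were chosen only after the results were seen.

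Among 66 genes and lists checked in the 4 clones, 4 genes had 1 clone far from the other 3, where chance gives about 1 in 20. The 4 are close to that share, so they are described only. S100A4, a calcium-binding protein, had an FPKM of 754 in Clone 3 and 1294 to 1392 in the others, a gap of 0.881 of the whole range on the log2 scale. C7orf23 had 4.49 in Clone 4 and 10.3 to 11.4 in the others, a gap of 0.886 of the range. SEC31B was listed at 2.48 in Clone 3 and at 0 in the others, and TTLL3 at 3.83 in Clone 2 and at 0 in the others. For both the equal values of 0 force the gap to be the whole range (1.000).

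The 870 genes that differ between clones and resistant populations are the first pattern weighed. Of the 35 splits of the 7 libraries 1, the real one, gave as many genes and the highest other gave 26, but the comparison was chosen because these libraries lay apart, and the distances between them gave 2 of 35 (exact permutation p = 0.057), so chance is not excluded independently. Length and GC bias is argued against by 865 genes after each library's trend was removed, depth by a Pearson correlation of 0.059 in size with the first component (exact permutation p = 0.887; Spearman 0.0, exact p = 1.0; 0.297 without the 2 libraries of most extreme depth), and values at 0 by 94.4% of the genes being above 0 in every library. With resistance group as a covariate the median difference was 0.916, against 0.98 without it, a ratio of 0.935. The genes were chosen for this difference in the same libraries, so the ratio cannot decide whether resistance group contributes. Fewer genes (226) then passed, with a median SE of 0.18 before and 0.186 after and residual degrees of freedom of 5 and 3. With population of origin as a block 11 passed (median size 0.949, SE 0.216). The cause of the lower counts was not tested. What also stays open is whether descent from 1 cell sets the clones apart or an unlabelled difference in culture or library preparation. Every clone was sorted and expanded and no population was, so these cannot be told apart.

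The 45 genes at least 2-fold lower in all 7 resistant libraries than in vehicle include CA9, ADM and SLC2A3. Values at 0 do not account for them, as 77.8% were above 0 in all libraries. Of the other libraries taken as the reference 2 gave as many genes or more, both of them clones (88 and 141). Among the 4 populations alone vehicle gave 95 genes and the highest other 42. In the other direction vehicle did not stand out, with 49 genes lower in it and 50 lower in the GNF-2 population. Some library of the 4 must come first, so the higher count is a description only. Vehicle also had the highest level of the glycolysis and hypoxia list, by 0.521 over the next library with all members. Without the 3 members among the 45 its median was still 0.383 above the next library (1.05 against 0.67). With all members vehicle was first for other lists too, among them adhesion (by 0.459), MAPK feedback (0.395) and FOXO targets (0.309). The glycolysis and hypoxia gap was the largest of these but not far above adhesion, so a difference in oxygen or glucose supply is not singled out. Days in culture were 7 for vehicle and 21 to 27 for the resistant populations, and are not given for the clones. Days and drug exposure go with the same library, and no test here parts them from resistance.

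The 4 genes called between catalytic-resistant and GNF-2-resistant libraries are all listed at 0 in some libraries (4 of 4), so how the software assigned overlapping transcripts is a candidate cause. The splits of 6 libraries into 3 and 3 number 10, too few for a share below 0.05; 2 of them gave at least 4 genes, and the highest other gave 555. That split set the 3 populations against the 3 clones and points to a structure of the samples. Differences between the classes at other genes stay open. On simulated data the test recovered 31 of 100 genes moved 2-fold and 85 of 100 moved 4-fold. Those data held no structure of clones and populations and no values listed at 0, so these shares need not hold here.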

How the results depend on the processing

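The alternatives restricted to genes above 0 in all 8 libraries, the length and GC correction, the covariate of resistance group, the block on population of origin, vehicle among the populations, list tests without each library or with clone as a covariate and distances permuted within kind were chosen only after the results were seen, as were all alternatives for clones against populations.

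Of 1772 values of named genes under the alternatives, 0 reversed, 1499 kept their side of the threshold, 256 lost it and 17 gained it. These genes were chosen because their groups did not overlap, so few of the alternatives could have reversed them. The count of 0 is therefore no evidence of stability. Of 968 list results under settings other than the estimated correlation, 847 kept their direction and their side, 30 lost and 16 gained the threshold, and 75 reversed. Among the 243 from lists that passed as reported 1 reversed, interferon response between the classes without Clone 1, where it did not pass (adjusted p = 0.589). Of the other 74, 1 passed, ribosomal proteins between the classes without Clone 1, higher in the catalytic-resistant group (adjusted p = 1.66e-05). FOXO targets kept the direction of the test in catalytic-resistant against vehicle with clone as a covariate, but their median went from -0.31 to 0.02. The estimated correlation took all 27 passing list results below the threshold, so 0 lists passed in each of the 4 comparisons.

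Called counts moved as follows, and where the setting does not itself change the genes or libraries tested the cause was not tested. Catalytic-resistant against GNF-2-resistant (4 genes) gave 2 at a mean FPKM of at least 5, 0 with genes above 0 in all libraries, 2 with the length and GC trend removed and 1 to 10 when each library was left out. Catalytic-resistant against vehicle (4) gave 59 with no filter (3 higher, 56 lower), 2 at a mean FPKM of at least 5, 1 rescaled, 1 with quantile normalization, 1 with robust variance, 0 at an adjusted p of 0.01, 0 with genes above 0 in all libraries and 0 to 1 with libraries left out. GNF-2-resistant against vehicle (11) gave 79 with no filter (6 higher, 73 lower), 7 at a mean FPKM of at least 5, 3 at an adjusted p of 0.01, 0 with genes above 0 in all libraries and 1 to 13 with libraries left out. Clones against populations (870) gave 117 at an adjusted p of 0.01, 1851 with vehicle among the populations, 226 with resistance group as a covariate, 11 with population of origin as a block and 120 to 1089 with libraries left out. Direction also moved with the pseudocount: 0.1 gave 6 higher and 0 lower for catalytic-resistant and 8 and 3 for GNF-2-resistant against vehicle, and 5 gave 0 and 3, and 4 and 9. List counts without each library were 2 to 7 between the classes, 9 to 11 and 7 to 10 against vehicle, and 1 to 3 for the clones. With clone as a covariate 5 lists passed between the classes and 8 and 6 against vehicle, and the distances between classes gave an exact permutation p = 0.111 within kind.

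The lists that reversed when a library was left out follow, with the range of camera adjusted p over the libraries left out. Between the classes these were adhesion (0.608 to 0.859), ATF4 (0.00468 to 0.975), cholesterol (0.0558 to 0.952), granulocyte (0.281 to 0.975), interferon (1.94e-05 to 0.589), lymphoid (0.05 to 0.993), mast cell (0.472 to 0.975), polycomb (0.226 to 0.975), histones (0.281 to 0.975), ribosomal proteins (1.66e-05 to 0.859), stem cell (0.772 to 0.993) and WNT (0.238 to 0.98). For catalytic-resistant against vehicle these were ATF4 (0.106 to 0.882), cholesterol (0.0418 to 0.994), epithelial and stromal (0.79 to 0.994), stem cell (0.615 to 0.996) and WNT (0.326 to 0.994). For GNF-2-resistant against vehicle these were ATF4 (0.0476 to 0.957), erythroid (0.708 to 0.991), interferon (0.0112 to 0.501), lymphoid (0.61 to 0.991), MHC class I (0.00443 to 0.878), p53 targets (0.89 to 0.991) and WNT (0.76 to 0.993). For clones against populations these were BCR-ABL and STAT5 (0.236 to 0.985), cholesterol (0.349 to 0.981), interferon (0.12 to 0.981), lymphoid (0.646 to 0.948), MAPK (0.263 to 0.952), mast cell (0.663 to 0.981), megakaryocyte (0.63 to 0.992), NF-kB (0.829 to 0.985), ribosomal proteins (0.00213 to 0.992) and stem cell (0.76 to 0.992). With clone as a covariate they were mast cell (0.951), ATF4 (0.609), ribosomal proteins (0.2) and histones (0.951) between the classes, ATF4 (0.589) and epithelial and stromal (0.617) for catalytic-resistant against vehicle and lymphoid (0.834), p53 targets (0.804) and ATF4 (0.603) for GNF-2-resistant against vehicle. With genes above 0 in all libraries they were mast cell (0.885) between the classes, erythroid (0.991), lymphoid (0.803) and p53 targets (0.991) for GNF-2-resistant against vehicle and mast cell (0.96) and WNT (0.96) for clones against populations. Rescaled they were lymphoid (0.931) for GNF-2-resistant against vehicle and megakaryocyte (0.988) and interferon (0.852) for clones against populations. The causes were not tested.

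For single libraries, an FPKM of at least 1 in the higher library gave 445 genes for imatinib against vehicle, 451 for nilotinib against imatinib and 1532 for Clone 1 against GNF-2. At least 20 gave 107, 166 and 295 for imatinib, nilotinib and GNF-2 against vehicle, 104 for nilotinib against imatinib, and 392, 507, 483 and 482 for Clones 1 to 4 against their origins. The 54 genes 2-fold from vehicle in all 7 libraries became 83 with a pseudocount of 0.1, 30 with one of 5 and 189 at 1.5-fold.

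The sample descriptions of the resistant populations end in a shared number and that of vehicle in another. No source used here says what these numbers mean, so no paired analysis was run. The block on origin uses the population each clone is said to come from, over 6 libraries. The alternative for count data was not run because the deposited values are FPKM. Values near an FPKM of 1 rest on about 40 to 81 fragments for a transcript of 2 kilobases, which limits low values most.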

Other observations

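ISG15, HGF and IKZF1 were chosen only after their values were seen, and no test was run in this part.

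Within the GNF-2-derived clones the interferon response differed. Relative to the GNF-2 population, Clone 1 was lower for 23 of 23 genes (median log2 difference -2.00), Clone 2 lower for 19 of 23 (median -0.81) and Clone 4 higher for 20 of 23 (median 1.18). The signs of RNA quality and selection also moved in Clone 4 against that population. Histones were higher for 6 of 8 (median 1.46) and ribosomal proteins lower for 20 of 20 (median -0.37, percentile 67.24, with the limit given above for Clone 4). IFI6, an interferon-induced mitochondrial protein, had an FPKM of 373 in the GNF-2 population, 38.7 in Clone 1, 213 in Clone 2 and 1009 in Clone 4. ISG15, a ubiquitin-like modifier, had 189, 46.4, 66.5 and 379 in the same order. IL1RAP, a receptor chain used to mark leukemic stem cells, had 46.0 in vehicle, 20.3 and 14 in the imatinib and nilotinib populations and 2.32 in Clone 2. PRG2, an eosinophil granule protein, had 59.3 in vehicle and 34.5 in the imatinib population and was listed at 0 in the other 6 libraries. The platelet glycoprotein GP9 had 119 in Clone 2 and 20.3 in Clone 3.

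In the comparison with each library as a reference in turn, Clone 2 had the most genes outside all others, 141 higher and 109 lower. The 70 entries with a value not given include genes of interest in leukemia. HGF, a growth factor, was listed at 0 in Clone 2, was not given in the nilotinib population, and lay between 37.1 and 82.8 in the other 6 libraries. IKZF1, the lymphoid regulator IKAROS, ranged from 4.70 in Clone 2 to 33.8 in Clone 4 among the 6 libraries with a value.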
